A study of Mus musculus with 6 samples.

How the data were processed

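Messenger RNA was measured by bulk sequencing in 6 libraries of bone marrow LSK cells from C57BL/6 mice. LSK cells are lineage-negative, Sca-1-positive, Kit-positive cells, the sorted fraction that holds hematopoietic stem cells and early multipotent progenitors. Per the labels' protocols, 3 libraries came from mice with ligature-induced periodontitis (LIP) and 3 from unligated mice (NL, no ligature), with marrow harvested on day 7. Each library pooled the cells of 3 mice, RNA was extracted with Trizol, and polyA-selected libraries were sequenced on a BGISEQ instrument as 100 bp paired-end reads, on average 45.0 M for each library, per the labels' protocols.

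The deposited table gave, for 16403 genes and each library, the authors' estimated counts (expected counts, not whole for part of the genes), their FPKM values and their TPM values. The FPKM and TPM were named as such in the deposited column headers. STAR, HTSeq and the mouse build GRCm38 are named in the submitters' processing notes, without versions or roles. The tool behind the deposited estimated counts is not given in the sources used here. Between 86.3% and 86.8% of the deposited estimated counts in a library were whole numbers, and 13481 genes had whole counts in all 6 libraries. A count with decimals was taken as a sign of reads divided between genes or copies, so genes without whole counts were read with more caution. The deposited table also held 6 columns of group means by the authors, which were not used. Some gene symbols in the table had been turned into calendar dates, and duplicated symbols were kept apart by their gene identifier.

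The test had been planned for whole counts, and the deposited counts turned out to be estimated counts, so they were rounded to whole numbers before the same test was run. Library totals ranged from 17780810 to 18841090 counts. At that depth 3 counts corresponded to between 0.159 and 0.169 CPM (counts scaled to the library total), a floor that covers counting error only. Genes were filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3, which kept 12564 genes and left out 3839, of which 20 were 0 in all libraries after rounding. Libraries were scaled with TMM factors, and LIP was compared with NL by edgeR's quasi-likelihood test with robust estimation and group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p below 0.05 was a call. Log2 fold changes are LIP over NL, with standard errors derived from the test statistic. CPM values are TMM-scaled, with mean ± SD over n = 3 libraries per group.

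In all, 33 gene lists were fixed before the data were examined. They covered blood cell types, cytokine and interferon responses, stress, cell cycle, metabolism, translation, adhesion and chromatin enzymes. Of their 818 symbols, 787 were found in the table and 763 were tested. The list of mitochondrially encoded respiratory chain genes had no member under its listed symbols and was not analysed here, leaving 32 tested lists. Each was compared with the other genes by camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists. Counts of called members are given over all tested genes and also adjusted over the list alone. List tests were repeated with the correlation estimated from the data, and with fry.

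The genes named in the text followed a rule written beforehand. It took the 12 largest rises and the 12 largest falls among called genes with an average log2 CPM of at least 1 and no overlap between the groups, leaving predicted models unnamed. It also took up to 4 members with the smallest p from each list, or 8 from a called list, and a fixed panel of progenitor and lineage genes. Plac8, Il1rl1, Hsp90ab1, Mmp9, Cxcr2, Ifitm6, Ly6g, Gata2, Vwf, Rhag, Ermap, Klf1, Car1, Gp1ba, Prss34, Ms4a2, Cma1, Socs2, Mcl1, E2f8, Lig1, Tipin, Cdca3, Nek2, Racgap1, Ccng2, Slc2a1, Calr, Pdia6, Ern1, Edem1, Ddit3, Manf and Kmt2a fall outside that rule and were chosen after their values were seen, to complete small counts. Gene positions are from RefSeq on GRCm38, matched by gene identifier for 16293 genes of the table.

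Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters on low counts, a replicate block, stricter thresholds, non-robust estimation and leaving out each library. After the data were seen, more were added. The first was an offset per library for the trend on effective transcript length, taken from the authors' deposited FPKM and counts. The next added an offset for GC content, known for 98.5% of tested genes from the longest GENCODE M21 transcript, and another used genes with whole counts only. List tests with each offset were also run with the estimated correlation. Both trends were lowess curves with a span of 0.3, fitted outside the ribosomal protein and respiratory chain lists.

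The edgeR gene calls, the length offset and camera at the preset correlation were tested on simulated data with the means, depths and dispersions of the LIP and NL libraries. Among 12493 simulated genes with 200 changed, 80% of those changed by 1.5-fold and 94% of those changed by 2-fold were recovered, and 3.23% of calls were false. Of those with the smallest simulated change, close in size to the median called change in LIP, 44% were recovered. With no change, 2 genes were called. A simulated length trend alone gave 1238 calls without the length offset and 0 with it. That trend was linear in log2 length and steeper than the observed slope difference between the groups, 0.0567 log2 per doubling. Neither count therefore carries over to these data. With 1 of 32 lists shifted, camera called that list and 1 other. Genes were simulated independently of each other, whereas the estimated correlation of the ribosomal protein list was 0.51. The simulation therefore could not show how camera at the preset correlation performs on lists of correlated genes. It also changed far fewer genes than the 3760 called in LIP. The GC offset, the estimated correlation, fry, DESeq2, limma-voom and the random lists were not tested this way.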

Results

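The study compared LSK cells, the stem and progenitor fraction of mouse bone marrow, between mice with ligature-induced periodontitis (LIP) and unligated mice (NL). In this model a ligature tied around a molar lets bacteria accumulate and causes local gum inflammation and bone loss. The comparison addressed how periodontitis affects the transcriptome of these progenitors, at a distance from the inflamed gum. Each group had 3 libraries, each pooled from 3 mice, with marrow taken on day 7. Library totals lay between 17780810 and 18841090 counts, and 12564 of the 16403 genes in the table were tested.

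LSK cells of LIP mice had higher levels of granulocyte-monocyte progenitor, neutrophil, monocyte and B-lineage mRNAs, in lists called at a preset inter-gene correlation. With an estimated correlation these calls were lost, with adjusted p of 0.0967, 0.0606, 0.12 and 0.0773 in that order. They had lower levels of heat shock, cholesterol synthesis, ribosomal protein and nuclear-encoded respiratory chain mRNAs. Of these only the heat shock call stayed with an estimated correlation, with adjusted p of 0.0606, 0.0967 and 0.12 for the other 3. With an offset for transcript length the ribosomal median went from -0.31 to -0.13 and the respiratory chain median from -0.22 to -0.07. Hspa1a and Hspa1b, which encode the inducible Hsp70 chaperone, fell most, to levels 37.7-fold and 31.7-fold below NL. These near-identical copies count as separate members of the heat shock list, and no list test left them out. That list was fixed as heat shock and sort stress genes, and handling of the groups was not tested. Most other changes were small, with a median absolute log2 fold change of 0.20 among called genes. In all, 3760 genes were called, 1776 higher and 1984 lower in LIP, but only 143 of the higher and 45 of the lower ones changed by at least 1.5-fold.

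Among the largest rises, Dgat2, an enzyme of triglyceride synthesis (chromosome 7, 99153663 to 99182713), rose from 3.17 ± 0.399 to 6.99 ± 0.912 CPM (SD, n = 3 per group), a log2 fold change of 1.14 ± 0.14 (SE). Chst1, a sulfotransferase, rose by 1.10 and Lef1, a transcription factor of Wnt signalling and lymphoid development, by 1.09 on the log2 scale. The eosinophil ribonuclease gene Ear1 rose by 1.08, and Ppbp, which encodes a platelet chemokine, by 1.03. Ear1 has near-identical relatives that can share reads. Ngp, a neutrophil granule gene (chromosome 9, 110419808 to 110423012), rose from 30.4 ± 3.42 to 60.1 ± 1.88 CPM, with an adjusted p of 1.01e-19. Mgam rose by 0.99, Cacna1h by 0.98, Pram1 by 0.96, Lin28a by 0.92 and the pre-B gene Vpreb3 by 0.92. Pou2af1, a B-cell coactivator, rose by 0.88, a 1.84-fold rise from 10.2 ± 0.502 CPM. In each of these genes all 3 LIP libraries lay above all 3 NL libraries, which was a condition for naming them.

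The heat shock list, fixed as heat shock and sort stress genes, had the largest mean change of the called lists, -1.08, because of Hspa1a and Hspa1b. Whether handling of the cells differed between the groups was not tested. Of 13 tested members, 11 fell and 1 rose, the same 11 and 1 when adjusted over the list alone, with a median log2 fold change of -0.41. Its adjusted camera p was 2.64e-72, and 0.00274 with an estimated correlation. Hspa1a (chromosome 17, 34969359 to 34972156) fell from 35.0 ± 1.27 to 0.926 ± 0.221 CPM and Hspa1b (chromosome 17, 34956429 to 34959238) from 81.8 ± 0.895 to 2.58 ± 0.588 CPM (SD, n = 3 per group). These 2 genes are near-identical copies without whole counts, so the split of reads between them is uncertain. They entered the list test as separate members, and no list test was run without them or with their counts summed. The co-chaperone genes Hsph1, Dnajb1 and Dnaja1 fell by 0.74, 0.69 and 0.66 on the log2 scale, and the abundant constitutive chaperone gene Hspa8 by 0.37. Hsp90ab1 stood at -0.01 with an adjusted p of 0.827.

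**Figure D1:**
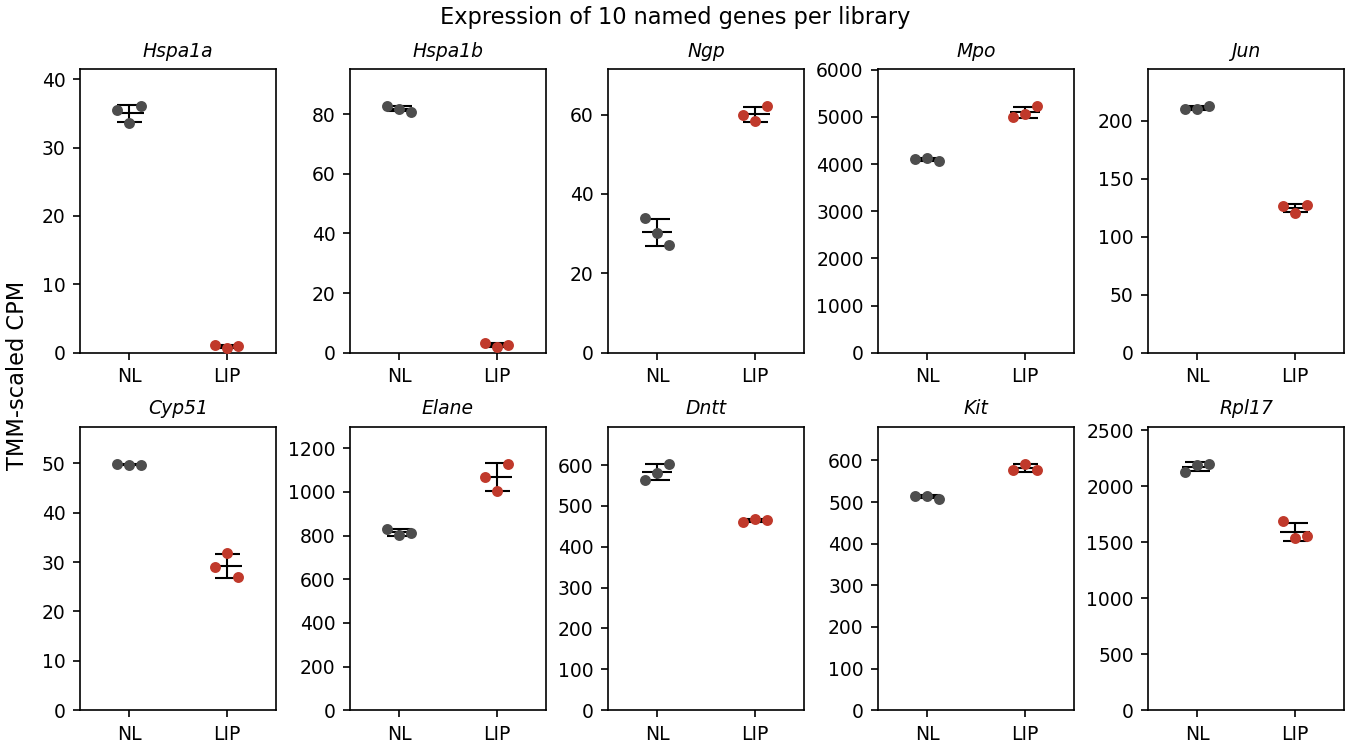
TMM-scaled CPM of 10 named genes in the 3 NL (grey) and 3 LIP (red) libraries; dots are libraries, the black mark is the group mean and the bar is 1 SD. Each vertical axis starts at 0. Hspa1b averaged 81.8 CPM in NL and 2.58 CPM in LIP, while Mpo averaged 4094 and 5095 CPM.

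Other large falls were in Cyp51, Jun, Msmo1 and Dynll1. Jun, an immediate-early transcription factor gene (chromosome 4, 95049036 to 95052222), fell from 211 ± 1.30 to 125 ± 3.75 CPM, with an adjusted p of 2.73e-26. Dynll1, which encodes a dynein light chain, fell by 0.71. At lower expression, LOC105242453 fell by 0.90, the zinc finger genes Zfp503 and Zfp973 by 0.79 and 0.76, the adhesion gene Chl1 by 0.76 and the histone gene Hist1h2bg by 0.69. LOC105242453, Zfp973, Dynll1 and Hist1h2bg lacked whole counts. Of the immediate-early list, 8 of 23 tested members fell and 2 rose, the same counts when adjusted over the list alone. Jund fell by 0.31, Fos by 0.31 and Dusp1 by 0.37, while Klf4 rose by 0.35. The other rise was in Fosl2, whose call was lost in 2 of 18 alternative fits. The list was called lower with an adjusted camera p of 0.00686, and the adjusted p was 0.372 with an estimated correlation. With total counts alone 5 members fell and 2 rose, and with the length and GC offset 9 fell and 1 rose. Relative to the NL mean of each gene, the list median was -0.0448 in NL-3 and -0.0229 in LIP-3, so the groups overlapped.

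Genes of granulocyte-monocyte progenitors rose together. Of 25 tested members 20 rose and 2 fell, or 21 and 2 adjusted over the list alone, with a median log2 fold change of 0.21. The adjusted camera p was 1.26e-13, and the adjusted p was 0.0967 with an estimated correlation. The primary granule genes Mpo (chromosome 11, 87793784 to 87804412) and Elane (chromosome 10, 79886312 to 79888216) were the most abundant named examples. Mpo rose from 4094 ± 33.9 to 5095 ± 116 CPM and Elane from 815 ± 14.2 to 1069 ± 62.6 CPM. Fcnb, a ficolin of the myeloid lineage, rose by 0.75 on the log2 scale. The transcription factor genes Irf8 and Spi1 rose by 0.28 and 0.16, and the receptor genes Csf1r and Csf3r by 0.43 and 0.27. Cebpa stood at 0.08 with an adjusted p of 0.111 and Cebpb at -0.05 with an adjusted p of 0.564. The 2 members that fell were Plac8 and Cd48, both by 0.15. Both calls were lost in 2 of 18 alternative fits, with the length offset and with the length and GC offset. Plac8 turned positive in both of these fits, at most to 0.01. Cd48 turned only with the length and GC offset, to 0.01.

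Most members of the mature neutrophil list rose in the same libraries. Of 15 tested members 12 rose and none fell, also when adjusted over the list alone, with a median of 0.68 and an adjusted camera p of 8.64e-15, but an adjusted p of 0.0606 with an estimated correlation. The 3 tested members that were not called were Mmp9, Cxcr2 and Ifitm6. Ly6g had between 0 and 3 counts per library and was not tested. The secondary granule genes Ltf, Lcn2 and Camp rose by 0.80, 0.78 and 0.74 on the log2 scale. S100a9 rose by 0.40, from 81.1 ± 7.92 to 107 ± 2.80 CPM, and S100a8 by 0.21. Over 18 alternative fits S100a9 ranged from 0.32 to 0.65 and S100a8 from 0.17 to 0.52. In the monocyte and macrophage list 6 of 15 members rose and 1 fell, also adjusted over the list alone, with F13a1 higher by 0.48 and the chemokine receptor gene Ccr2 by 0.39. The fall was in C1qb, by 0.37, and its call was lost in 10 of 18 alternative fits, which gave log2 fold changes from -0.51 to -0.25. The adjusted camera p of the list was 5.54e-04, and the adjusted p was 0.12 with an estimated correlation. The sort was meant to exclude mature cells of these lineages.

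B-lineage genes rose at low expression. Of 12 tested members 7 rose and none fell, or 8 and 0 adjusted over the list alone, with a median of 0.38. The transcription factor genes Pax5 and Ebf1 rose by 0.74 and 0.60, and Igll1, a surrogate light chain gene, by 0.41. The adjusted camera p was 4.69e-05, and the adjusted p was 0.0773 with an estimated correlation. Of 7 tested plasma cell markers 4 rose, also adjusted over the list alone, Jchain by 0.36, Mzb1 by 0.55, Derl3 by 0.63 and Prdm1, whose call was lost in 8 of 18 alternative fits. That list had an adjusted camera p of 0.00461 and an adjusted p of 0.163 with an estimated correlation. In the dendritic cell list 2 of 13 members rose, also adjusted over the list alone, Cd74 by 0.31 and Siglech by 0.60. With the length offset 5 members rose, and 4 did with total counts alone and with the length and GC offset. Its adjusted camera p of 0.0445 became an adjusted p of 0.368 with an estimated correlation and 0.075 with total counts alone. The dendritic call was also lost without NL replicate 1, NL replicate 2 or LIP replicate 3, with adjusted p of 0.0667, 0.0575 and 0.0995.

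Other cell type lists were not called. Of 27 stem cell identity genes 5 rose and 6 fell, or 5 and 8 adjusted over the list alone, with a median of -0.02 and an adjusted p of 0.751. There were 6 higher and 4 lower with total counts alone, and with the length and GC offset 2 and 5. Mycn fell by 0.31, and Meis1, Sult1a1, Gata2 and Vwf were among those that rose, although the call of Vwf was lost in 5 of 18 alternative fits and that of Gata2 in 1. Of 21 lymphoid-primed progenitor genes 9 rose and 7 fell, or 10 and 7 adjusted over the list alone, with a median of 0.05 and an adjusted p of 0.319, and with the length offset 5 rose and 5 fell. Dntt, the terminal transferase gene of early lymphoid cells, fell from 583 ± 19.7 to 464 ± 4.15 CPM, while Cecr2 rose by 0.77. Erythroid markers went both ways, with 3 of 17 higher and 5 lower, or 3 and 6 adjusted over the list alone, and an adjusted p of 0.491. Slc4a1, Rhag and Ermap rose, while Car2 fell by 0.20 and Aqp1, Klf1 and Car1 were also among those that fell. The calls of Ermap, Klf1 and Car1 were lost in 6 of 17, 5 of 18 and 2 of 18 alternative fits. With total counts alone 4 of the 17 rose and 4 fell, with the length offset 5 and 3, and with the length and GC offset 5 and 6. Of 14 megakaryocyte and platelet genes 5 rose, or 6 with 1 lower adjusted over the list alone, with an adjusted p of 0.0539. The list was called higher without LIP replicate 2 (0.0353) and with the length offset (0.0274). Selp, Itgb3, Nbeal2 and Gp1ba rose alongside Ppbp, although Nbeal2 lost its call in 2 of 18 alternative fits and Gp1ba in 3.

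T and NK cell markers had 3 of 12 members higher, also adjusted over the list alone, with an adjusted p of 0.142. These were Il2rb, Cd3e and Cd4, whose calls were lost in 2 of 18, 1 of 17 and 6 of 18 alternative fits. In the list of mast cells, basophils and eosinophils 4 of 13 rose and 3 fell, or 5 and 3 adjusted over the list alone, with an adjusted p of 0.391. The eosinophil granule genes Epx and Prg2 rose by 0.63 and 0.29, with Hdc and Prss34, and the mast cell genes Cpa3, Ms4a2 and Cma1 fell, the last 2 with calls lost in 2 of 18 and 3 of 16 alternative fits. The median of that list was 0.08 and its mean -0.02. With the length and GC offset its median was 0.21 and it was called higher, with an adjusted p of 0.0314, or 0.207 with an estimated correlation as well. Of 8 stromal and endothelial genes 2 rose and 2 fell, also adjusted over the list alone, with an adjusted p of 0.455. Pdgfrb and Vcam1 rose, and Postn and Emcn fell, although Emcn lost its call in 8 of 18 alternative fits.

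Of the remaining panel genes, Kit rose by 0.18 and Ly6a, which encodes Sca-1, stood at -0.07 with an adjusted p of 0.386. Both proteins were used to select the cells. Cd34 stood at -0.04, Flt3 at 0.08, Slamf1 at 0.15, Il1r1 at 0.05, Mki67 at 0.07, Gata1 at -0.04 and Pf4 at -0.20, none of them called. Flt3 and Pf4 came closest, with adjusted p of 0.0514 and 0.0527. Il6ra rose by 0.20. Il1b had between 2 and 7 counts per library and was not tested, so a difference was not detectable at this depth.

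Innate and cytokine receptor genes rose more often than they fell. Of 30 tested members 11 rose and 2 fell, also adjusted over the list alone, with a median of 0.07 and an adjusted camera p of 5.54e-04, but an adjusted p of 0.12 with an estimated correlation. The median was 0.13 without NL replicate 1 and 0.12 without LIP replicate 1, and 0.11 with total counts alone. Relative to the NL mean of each gene, the list median was 0.0197 in LIP-1 and 0.0219 in NL-1, so the groups overlapped. Csf1r, Csf2ra and Csf3r, which rose, are also in the granulocyte-monocyte progenitor list. Csf2rb and Csf2rb2, subunits of receptors for IL-3, rose by 0.44 and 0.63 and share reads, Ifngr1 by 0.27 and Tnfrsf1b by 0.25. Il18r1 fell by 0.44, and the other fall was in Il1rl1, whose call was lost in 8 of 18 alternative fits. Of 20 homing and adhesion genes 9 rose and 1 fell, or 11 and 1 adjusted over the list alone, with an adjusted camera p of 0.00409 and an adjusted p of 0.115 with an estimated correlation. The integrin genes Itgam and Itgb2 rose by 0.35 and 0.23 and Pecam1 by 0.27, while the retention receptor gene Cxcr4 fell by 0.14.

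Interferon-gamma response genes fell more often than they rose. Of 31 tested members 14 fell and 1 rose, also adjusted over the list alone, with a median of -0.12 and an adjusted camera p of 3.3e-04, but an adjusted p of 0.163 with an estimated correlation. The guanosine triphosphatase genes Iigp1, Irgm2 and Igtp fell by 0.53, 0.35 and 0.28, the transcription factor gene Irf1 by 0.23, and Tapbp rose by 0.15. Tgtp1 and Tgtp2 fell by 0.45 and 0.42 but share reads. With total counts alone the list had 9 members lower and 6 higher. Of 34 type I interferon genes 7 fell and none rose, also adjusted over the list alone, among them Rtp4 by 0.41 and Stat2 by 0.21, with an adjusted p of 0.0539. That list was called lower without NL replicate 2 (0.0492) or LIP replicate 2 (0.0479), and with total counts alone 6 members fell and 2 rose. Of 26 IL-1, TNF and NF-kB response genes 3 fell, or 2 adjusted over the list alone, Nfkbia, Nfkbiz and Nfkb2. Nfkbia fell by 0.17, and the calls of Nfkbiz and Nfkb2 were lost in 2 and 10 of 18 alternative fits. Their median was 0.01, their mean -0.02 and the adjusted p 0.971. Total counts alone gave 2 falls and 2 rises, and the length and GC offset 3 and 3. The IL-6, G-CSF and STAT3 list had 7 of 19 members higher and 3 lower, also adjusted over the list alone, with an adjusted p of 0.133. Hp rose by 0.47, and Cish, a feedback inhibitor of STAT5 signalling, fell by 0.63, with Socs2 and Mcl1, whose calls were lost in 1 and 5 of 18 alternative fits.

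Cholesterol synthesis genes fell as a group. Of 26 tested members 20 fell and none rose, or 22 and 0 adjusted over the list alone, with a median of -0.35. The adjusted camera p was 3.11e-21, and the adjusted p was 0.0606 with an estimated correlation. Cyp51, the sterol demethylase gene (chromosome 5, 4080674 to 4104697), fell from 49.8 ± 0.186 to 29.3 ± 2.40 CPM, and Msmo1 from 29.3 ± 1.13 to 17.5 ± 1.01 CPM. Idi1 fell by 0.69, Insig1 by 0.59 and Fdps by 0.40. The fatty acid list was not called, with 2 of 25 members higher and 2 lower, also adjusted over the list alone, and an adjusted p of 0.446, while 2 rose and 5 fell with the length offset. In it Cpt1a, which admits fatty acids to mitochondria, rose by 0.33 and the desaturase gene Scd2 fell by 0.27. The other rise was in Acsl1 and the other fall in Acsl4, whose call was lost in 1 of 18 alternative fits.

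**Figure D2:**
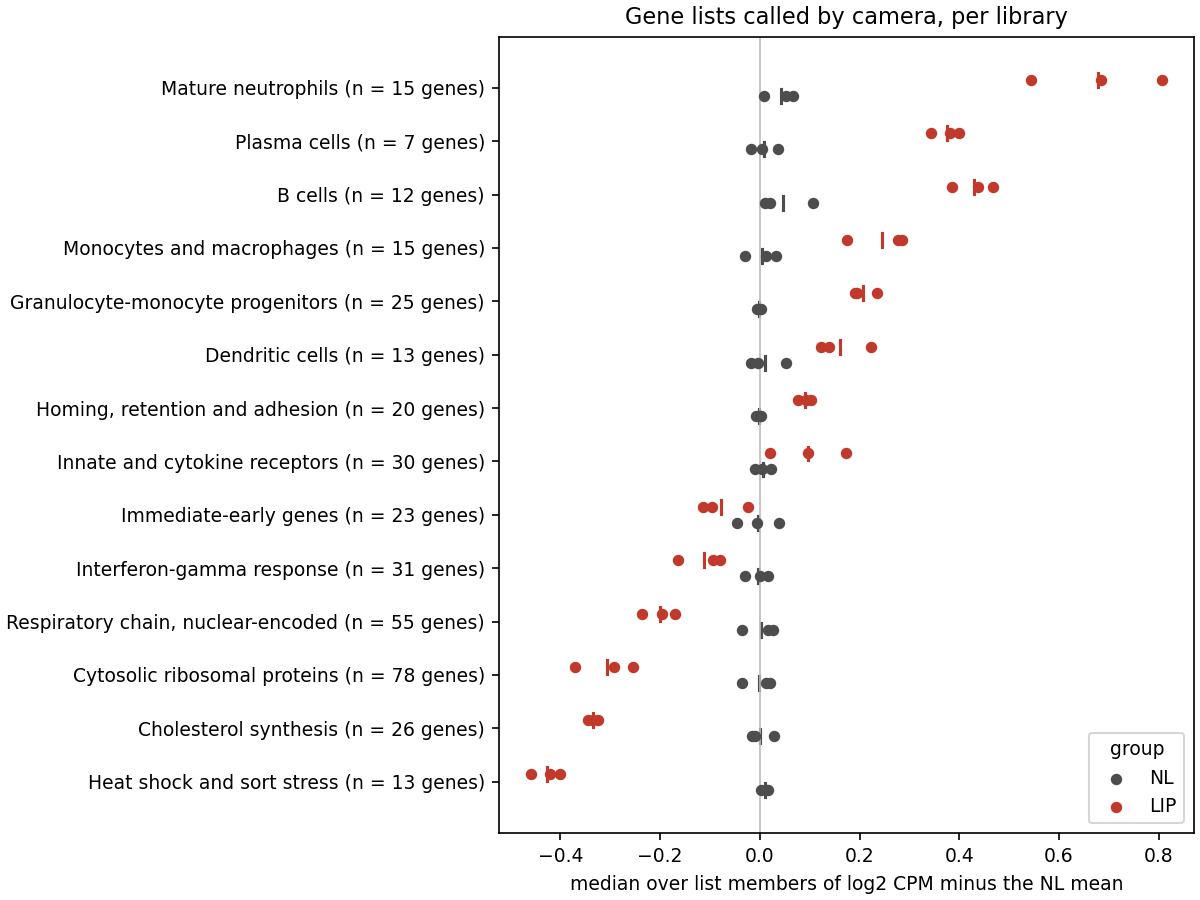
Median over list members of log2 CPM minus the NL mean, for each of the 14 lists called by camera, in NL (grey) and LIP (red) libraries; dots are libraries, vertical ticks are group means over n = 3, and n beside each name counts tested genes. The LIP mean was 0.68 for mature neutrophils and -0.43 for the heat shock list.

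Ribosomal protein genes were lower almost without exception. Of 78 tested members 77 fell, or 78 adjusted over the list alone, with a median of -0.31, an adjusted camera p of 1.13e-77 and an adjusted p of 0.0967 with an estimated correlation. Rpl17 fell by 0.45 and Rps20 by 0.39. Only 60 of the 78 genes had whole counts, and the family has many pseudogenes that can share reads. Of 55 nuclear-encoded respiratory chain genes 44 fell, or 49 with 1 higher adjusted over the list alone, with a median of -0.22, an adjusted camera p of 4.8e-24 and an adjusted p of 0.12 with an estimated correlation. Ndufa4 fell by 0.42 and Cox7b by 0.36. Fold changes also followed transcript length outside these lists. Other genes with an effective length under 500 bases had a median log2 fold change of -0.24, those from 500 to 1000 bases -0.14, and those over 5000 bases 0.04. With an offset for that trend the ribosomal protein median was -0.13 with 55 members lower, at an adjusted camera p of 1.05e-24, but 0.1 with an estimated correlation. The respiratory chain median was then -0.07 with 22 lower and 1 higher, at an adjusted camera p of 2.52e-04, but 0.199 with an estimated correlation.

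**Figure D3:**
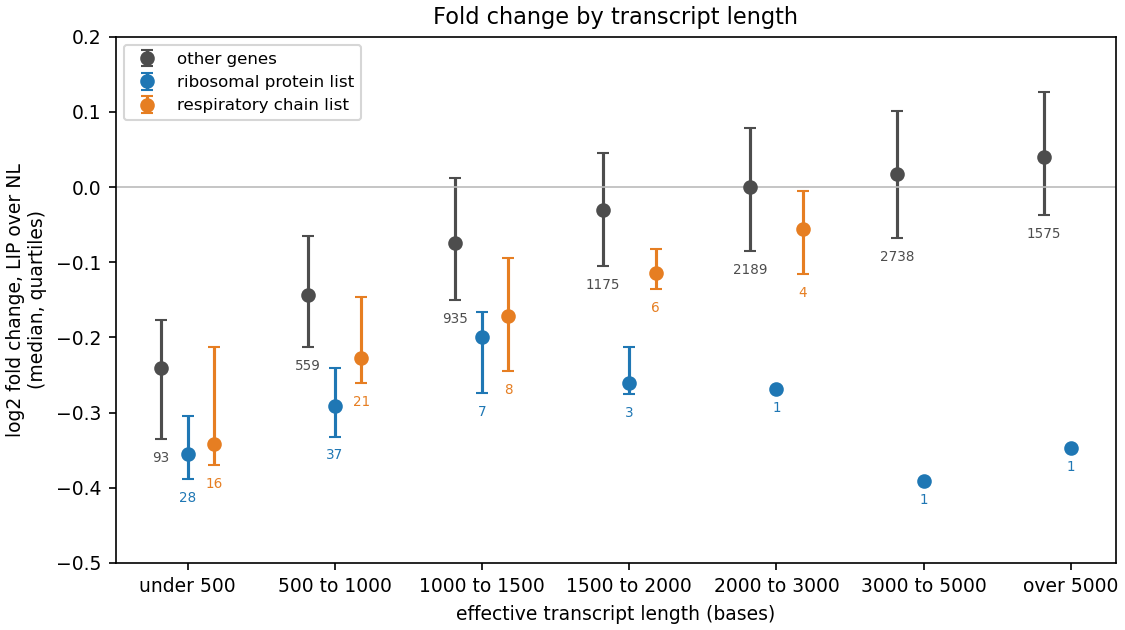
Median log2 fold change of LIP over NL by effective transcript length in bases, for genes outside both lists (grey), ribosomal protein genes (blue) and respiratory chain genes (orange); bars span the quartiles and small numbers count genes. Among other genes the median ran from -0.24 under 500 bases to 0.04 over 5000 bases. Ribosomal protein bins above 1000 bases hold between 1 and 7 genes each.

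Cell cycle and further metabolic lists were not called. Of 40 G1/S genes 5 rose and 9 fell, and of 46 G2/M genes 4 rose and 8 fell, also adjusted over each list alone, with adjusted p of 0.446 and 0.407. With total counts alone 10 rose and 8 fell of the former and 8 and 8 of the latter, with the length offset 5 and 10 against 6 and 9, and with the length and GC offset 6 and 11 against 6 and 5. Clspn and Pole rose by 0.36 and 0.24, with E2f8, Lig1 and Tipin, and of the G2/M genes Aurkb, Cdca3, Nek2 and Racgap1 rose. The call of Lig1 was lost in 1 of 18 alternative fits. Pcna and Cdk1 fell by 0.25 and 0.23. Of 16 inhibitor and quiescence genes 2 rose and 4 fell, or 2 and 5 adjusted over the list alone, with an adjusted p of 0.446. Rb1 and Klf4 were higher and Cdkn1b, Trp53inp1 and Ccng2 among those lower. With total counts alone 2 rose and 3 fell, and with the length and GC offset 2 and 7. Of 23 glycolysis genes 6 rose and 3 fell, also adjusted over the list alone, with an adjusted p of 0.391. Total counts alone gave 9 rises and 1 fall, and the length and GC offset 4 and 4. Hk2 rose by 0.33, and Tpi1, Slc2a1 and Ldha fell, the last 2 with calls lost in 3 and 1 of 18 alternative fits. MYC target and ribosome biogenesis genes had 8 of 36 higher and 7 lower, also adjusted over the list alone, with a median of 0.02, a mean of -0.001 and an adjusted p of 0.925. Total counts alone gave 11 rises and 4 falls, the length offset 6 and 5, and the length and GC offset 2 and 5. Of 22 unfolded protein response genes 5 rose and 5 fell, or 6 and 6 adjusted over the list alone, with an adjusted p of 0.491, and 8 rose and 5 fell with total counts alone. Herpud1 and Dnajb9 fell by 0.38 and 0.46, with Hspa5, Ddit3 and Manf. Hyou1 rose by 0.15, with Calr, Pdia6, Ern1 and Edem1, although Calr and Edem1 lost their calls in 2 and 5 of 18 alternative fits. The median of that list was 0.003, its mean -0.04 and its camera direction lower. Histone and DNA methylation enzymes had 9 of 26 members higher and 1 lower, or 10 and 3 adjusted over the list alone, with an adjusted p of 0.0928, and Asxl1 and Dnmt1 rose by 0.20 and 0.18 while Kmt2a fell. With the length offset 5 rose and 6 fell, and with the length and GC offset 3 and 5. With total counts alone 13 rose and 1 fell and the list was called, with an adjusted p of 0.0268, as it was without NL replicate 1 (0.0405) or LIP replicate 1 (0.0372).

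The calls rest on edgeR's quasi-likelihood test of 3 against 3 libraries. DESeq2 called 2376 genes, 1091 higher and 1285 lower. Of the edgeR calls 47.2% were higher in LIP, against 67.9% with total counts alone. The groups did not overlap in 5142 tested genes, or 40.9% where chance gives 10%, and in 3488 of the called genes. Libraries of 1 group differed from each other by 1.69 to 2.68 times counting noise per degree of freedom, and libraries of different groups by 7.33 to 13.3 times. Within a group the ratio was only 1.07 to 1.14 for genes with low counts, and 4.95 to 10.4 for genes with high counts. No library was counted as a repeat of another, but these values cannot tell separate pools from repeat libraries of 1 pool. The common biological coefficient of variation was only 2.80%, and p-values measure only the spread between these libraries, which may be technical. Camera called 14 lists, 8 higher and 6 lower, but with an estimated correlation only the heat shock list, and other splits of the libraries, which mix the groups, gave between 5 and 12 camera calls.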

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

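Of the tests here, the length offset, the length and GC offset, both of these with an estimated correlation, and the use of whole-count genes were chosen after the result was seen. Under limma-voom, RLE or upper-quartile factors, no filter on low counts, a CPM filter and non-robust estimation, called genes stayed between 3635 and 3780. Whole-count genes alone gave 3181 calls, the length offset 3358 and the length and GC offset 3069. Of the 3760 calls, 2882 were also made in the same direction with the length offset, 1 in the opposite direction. Fewer genes were called by DESeq2 (2376, with 1091 higher and 1285 lower), which kept 62.9% of the calls; the cause was not tested. An adjusted p below 0.01 left 2493 genes, 1148 of them higher, and a fold change of at least 1.5 left 188, 143 higher and 45 lower, by construction. Total counts alone gave 2756 higher and 1301 lower genes, with the median of all genes shifted by 0.0436. That scaling gave medians of 0.0250 for the stem cell, 0.0935 for the lymphoid-primed and 0.259 for the granulocyte-monocyte list, against -0.0193, 0.0492 and 0.215 with TMM factors. The length offset gave 0.0155, 0.0612 and 0.278, and the length and GC offset -0.0308, 0.0405 and 0.261.

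The replicate numbers were not paired in the labels, and deviations of libraries with the same number correlated at 0.03, -0.02 and -0.11. A replicate block gave 3729 calls, 1750 higher and 1979 lower, and the same 14 lists.

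Without 1 library, calls ranged from 2987 to 3397, with 1437 to 1590 higher and 1550 to 1807 lower, and list calls from 13 to 16. Medians then ranged from -0.0439 to 0.0221 for the stem cell list, 0.0471 to 0.0724 for the lymphoid-primed list and 0.174 to 0.239 for the granulocyte-monocyte list. An estimated correlation left 1 list, and fry, which does not compare a list with other genes, called 23. The length offset called 15, the added list being megakaryocytes and platelets. The length offset with an estimated correlation called 5 lists (granulocyte-monocyte progenitors, neutrophils, B cells, heat shock and cholesterol), and the length and GC offset with it called the same 5.

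Of 180 called genes named by the rule, 29 lost the call in at least 1 of 18 fits and 2 reversed. These were Cd48 (0.0105) and Cox7c (0.0352), both with the length and GC offset. This tally leaves out the genes chosen after their values were seen. Among those, Plac8 reversed in 2 fits and several lost calls, such as Il1rl1 in 8 fits and Ermap in 6. Uncalled genes that reversed were Cd34 (0.00159 with total counts alone, 0.0157 with the length and GC offset) and Ly6a (0.05003 with the length offset, 0.0468 with the length and GC offset). No called list reversed. Uncalled lists turned their camera direction at medians of 0.0579 (total counts), 0.0135 (fry), 0.0274 (length offset) and -0.0126 (length and GC offset) for NF-kB, and 2 of the 6 fits without 1 library turned it too, with medians from 0.00673 to 0.0319 over all 6. MYC targets turned at 0.0159 with fry and 5.06e-04 with the length and GC offset, and in 2 of 6 fits without 1 library, with medians from 0.0109 to 0.0248. Erythroid genes turned at -0.0222 with the length offset, and G2/M (0.00341) and methylation enzymes (0.00556) with the length and GC offset. The causes were not tested.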

Other observations

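The tests of length, fragment length, shared reads, LSK share, neutrophil markers, progenitor genes and glucocorticoid genes, the 5 lists in this part, the counts over members not seen beforehand, the list medians per library with the offsets and the offsets with an estimated correlation were chosen after the result was seen; those of GC content, Rbm3, clock genes and other splits were set before their values were looked at.

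Some chaperone genes outside the fixed list moved with it. Of 13 further targets of the heat shock factor HSF1, 8 fell and none rose, among them Chordc1 by 0.59, Dnaja4 by 0.52, Cacybp by 0.51 and Hspa4l by 0.41, but these 4 had been seen lower when the list was drawn up. Of the 9 not seen beforehand 4 fell, with an adjusted camera p of 0.00824, and 0.131 with an estimated correlation. Of 10 eosinophil-associated genes 7 were called higher, among them Epx by 0.63, Alox15 by 0.82 and Ear6 by 0.79, but 5 of the 7 had been seen higher beforehand. Of the 5 not seen beforehand 2 rose, with an adjusted camera p of 0.236. The Ear genes can share reads, and Ccr3 (-0.11), Prg3 (0.24) and Il5ra (0.48) were not called.

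Glucocorticoid-induced genes gave no clear lead. Of 14 tested genes 7 fell and 2 rose, with Tsc22d3 lower by 0.43, Per1 by 0.29 and Mt2 by 0.29, and Fkbp5 and Tle3 higher by 0.10 and 0.14. Of the genes that fell, 3 had been seen lower before the list was drawn up. Among the 11 others 4 fell and 2 rose, with a median of 0.05 and an adjusted camera p of 0.945, so a lower glucocorticoid response in LIP stays undecided.

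The fall of Hspa1a and Hspa1b in LIP was the largest change among called genes. Reads moved between the copies are excluded, since their summed counts fell by 5.05 on the log2 scale, from at least 115 CPM in every NL library to at most 4.3 CPM in every LIP library. A difference in cell temperature before lysis may be involved and stays open: of the cold-inducible genes Cirbp rose by 0.49, seen before the test was set, while Rbm3 stood at -0.0697 with an adjusted p of 0.116. A difference in the time of day of harvest also stays open, with 2 of 15 core clock genes, Nr1d1 and Bhlhe41, called at an absolute log2 fold change of at least 0.3. Handling of each group on its own and a response to periodontitis were not tested, and the labels give no harvest times or batches.

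Ribosomal protein and respiratory chain genes fell in LIP together with other short transcripts. Length as the whole cause is argued against, because with the length offset the medians were still -0.131 and -0.0691, with 55 of 78 and 22 of 55 members called lower and no overlap of the list medians per library between LIP and NL; length and GC content together left the ribosomal protein median at -0.147, also without overlap. Both lists were called with the length offset at the preset correlation only, with adjusted p of 0.1 and 0.199 with an estimated correlation. A difference in fragment length is argued against as the source of the length trend, since it was 2.42 bp (exact permutation p = 0.6, two-sided) with overlapping groups while the length slopes did not overlap (p = 0.1, the smallest possible). A response to periodontitis, RNA integrity and library preparation remain possible explanations, untested, and much of each fall, from -0.31 and -0.22, went with length. Translation capacity was not measured.

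Neutrophil granule genes rose in LIP. A lower share of LSK cells, raising every other cell type alike, stays open as the whole cause. The neutrophil list was tested after it had shown the largest median of the cell type lists, 0.68, in these same libraries. The permutation p below does not account for that choice and takes markers from the same libraries as independent, so it cannot decide. Over markers with an average log2 CPM from 0 to 3, the median of 7 neutrophil markers was 0.67. It exceeded that of 48 markers of other lineages, 0.30, by 0.365 (permutation p = 0.022), and the medians per LIP library did not overlap. This window was chosen with the values in view, and of 9 windows 8 gave a difference above 0.2 with a permutation p under 0.05 and no overlap, while log2 CPM from 1 to 3, with 5 neutrophil markers, gave 0.18 (permutation p = 0.266) with overlap. A lower LSK share as part of the rise also stays open, since 12 of the 48 other markers rose and 2 fell. Their medians were 0.55 for plasma cells and 0.43 for megakaryocytes, against 0.16 for dendritic, 0.08 for stromal and -0.05 for mast cell, basophil and eosinophil markers. More neutrophil-lineage cells in the sorted population may account for the neutrophil rise, since 7 of 7 abundant neutrophil markers were higher. The rise was uneven, as S100a8 and S100a9, both among the 7, rose by only 0.21 and 0.40, against a list median of 0.68. All 7 also belong to the list that showed the pattern. A granulocyte-monocyte program raised within LSK cells is also consistent with 20 of 25 progenitor genes being higher, and both stay open, since sums over sorted cells do not show which cells carried the transcripts.

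Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many genes (3760 in all, 1776 higher and 1984 lower), and the highest other split called 0 with edgeR, with between 140 and 303 genes at an unadjusted p under 0.05 in the other splits. For lists, 1 split called as many as the real 14, and the highest other called 12. With 10 splits no share under 0.05 can be reached. Each other split set 2 libraries of 1 group with 1 of the other, and of these 9 splits the ribosomal protein and cholesterol lists were called in 9, respiratory chain in 8, neutrophils in 7, granulocyte-monocyte progenitors and B cells in 6 each and heat shock in 5. Such splits keep part of any difference between the groups, so these calls are no measure of false ones.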
